A study of Homo sapiens with 12 samples.

How the data were processed

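RNA from HepG2 cells, an established human line derived from a hepatoma, was measured by sequencing in 12 libraries, 3 in each of 4 groups. Per the labels, cells were kept for 24 h in medium with charcoal-stripped serum and then treated for 24 h with vehicle (DMSO, 0.1%), dexamethasone (Dex, 50 nM), KLA (labelled dose 100 ng/µl) or both (DexKLA). The unit of the KLA dose was taken as labelled and could not be checked. The labels give a DMSO percentage for the vehicle group alone and do not say whether treated cells also received DMSO. The labels do not state whether the replicates of a group were separate cultures. The p-values below therefore measure only the spread between these libraries, which may be technical. The strand of the libraries was not given in the sources used here, and antisense reads cannot be separated, so genes that overlap a named gene are named beside it.

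The submitters' processing notes name Trimmomatic, BWA 0.7.17 and HOMER 4.10 with the hg38 genome, without saying what each program did. The deposited values for 70507 RefSeq transcripts came in steps of 0.5. How they were made was not given in the sources used here, and these deposited values were taken to be expected counts. Between 32.6% and 36.4% of a library's values were not whole numbers. The counts were rounded to whole numbers. Transcripts with no gene symbol (406, holding 1.71% to 2.55% of a library's total over all transcripts) were left out of the gene tests, since their reads cannot be assigned to a named gene. For each of the 28256 gene symbols the transcript with the highest total over all libraries was kept, which decided the choice for the 12552 genes with more than 1 transcript. Transcript positions were checked against RefSeq gene models for 12658 of the 13166 genes tested below, of which 12643 lay on the same chromosome, 10974 lay inside the gene model and 8477 had the same start. Among the tested genes, 742 had a transcript with several annotated loci. Their reads cannot be assigned to 1 locus.

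Genes were tested with edgeR 4.0.16 in R 4.3.3, and the file was read with the data.table package, version 1.17.8. Low counts were removed with filterByExpr (minimum count 10), which left 13166 genes. Libraries were scaled with TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom), and p-values were adjusted by Benjamini and Hochberg's method over the tested genes of each comparison. A gene was called at an adjusted p under 0.05. The 8 comparisons were Dex versus DMSO, KLA versus DMSO, DexKLA versus DMSO, DexKLA versus KLA, DexKLA versus Dex, the mean effect of Dex over cells without and with KLA, the mean effect of KLA over cells without and with Dex, and the interaction of both. Levels are given as TMM-normalised CPM, mean ± SD over 3 libraries, and log2 fold changes as the fitted value ± standard error. Raw levels per library and limits for counts near 0 (3 counts) use the plain library total, and such limits cover counting error only. For HIF3A, with 1 to 3 counts in each library without Dex, the ratio of pooled counts over pooled totals is given with its exact 95% binomial interval, a step added after the data were seen. Principal components were computed on log2 CPM with a prior count of 2.

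The rule for naming genes, the gene lists, the comparisons and the first set of alternatives were chosen before the data were examined. For each comparison with DMSO, the rule named the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 and all 3 treated libraries beyond all 3 DMSO libraries. It also named up to 4 called members of each list, and 6 receptor and response genes whether or not they were called. For the other comparisons it named the 5 called genes with the smallest p-values in each direction. Where a gene lies outside the rule, the text says that it was chosen after its values were seen. The 28 lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 26 lists with at least 5 tested members, and again with the correlation estimated. Members were also adjusted over the list alone.

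The alternatives chosen beforehand were the size factors of DESeq2 1.42.0 in the edgeR model, library size alone, the DESeq2 and limma voom tests, no filter, a filter of 50 reads in 3 libraries, a replicate block, the longest transcript per gene, the 6 libraries of a comparison alone, and leaving out each library in turn. The alternatives chosen after seeing the data were thinning each library to 3317739 counts, removing each library's smooth trend on transcript length and GC content (loess span 0.3, 12926 genes with a GC value, 98.2% of those tested), the depth class of the library (the 6 deeper or the 6 shallower libraries) as a covariate, libraries of 1 depth class alone, and leaving out the pair of libraries farthest apart on the first principal component. Their effects are given in the closing section. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

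Counts over gene symbols ran from 3317739 to 20933489 per library, a 6.31-fold range. In a test on simulated data with the depth and spread of these libraries, a 2-fold change was called for 83.6% of genes in Dex versus DMSO, 82.1% in KLA versus DMSO, 79.1% in DexKLA versus DMSO, 88.1% in DexKLA versus KLA and 89.6% in DexKLA versus Dex. The shares were 97% for the mean effect of Dex, 94% for that of KLA and 68.7% for the interaction. For a 1.5-fold change they were 43.3% in KLA versus DMSO and 26.9% for the interaction.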

Results

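HepG2 cells treated with vehicle, dexamethasone (Dex), KLA or both were compared for gene expression. Dex is a synthetic glucocorticoid that activates the glucocorticoid receptor. The labels do not spell out KLA. The lipopolysaccharide receptor genes were looked at because KLA is also the usual short form of a lipid A that activates TLR4, a reading that the labels do not settle.

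Total counts over genes were 3317739, 5277462 and 4409645 in DMSO replicates 1 to 3, 3642689, 17782048 and 4613813 with Dex, 15998665, 20933489 and 18614372 with KLA, and 9289768, 4514613 and 11484487 with DexKLA. Every KLA library was thus deeper than every DMSO library. The first principal component held 27.9% of the variance and the second 14.7%. On the first, the DMSO libraries lay from −39.6 (replicate 1) to −15.6 and all others from −5.49 to 23.4 (KLA replicate 3). Libraries also differed in a trend with transcript length. Across genes, which are not independent replicates, Spearman's rho between length and a library's deviation from the mean of all 12 ran from 0.192 to 0.395 with DMSO, −0.534 to 0.137 with Dex, −0.526 to −0.152 with KLA and −0.134 to 0.385 with DexKLA. No pair of replicates was a copy, with a chi-square per degree of freedom of at least 1.88 between replicates of a group.

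**Figure D1:**
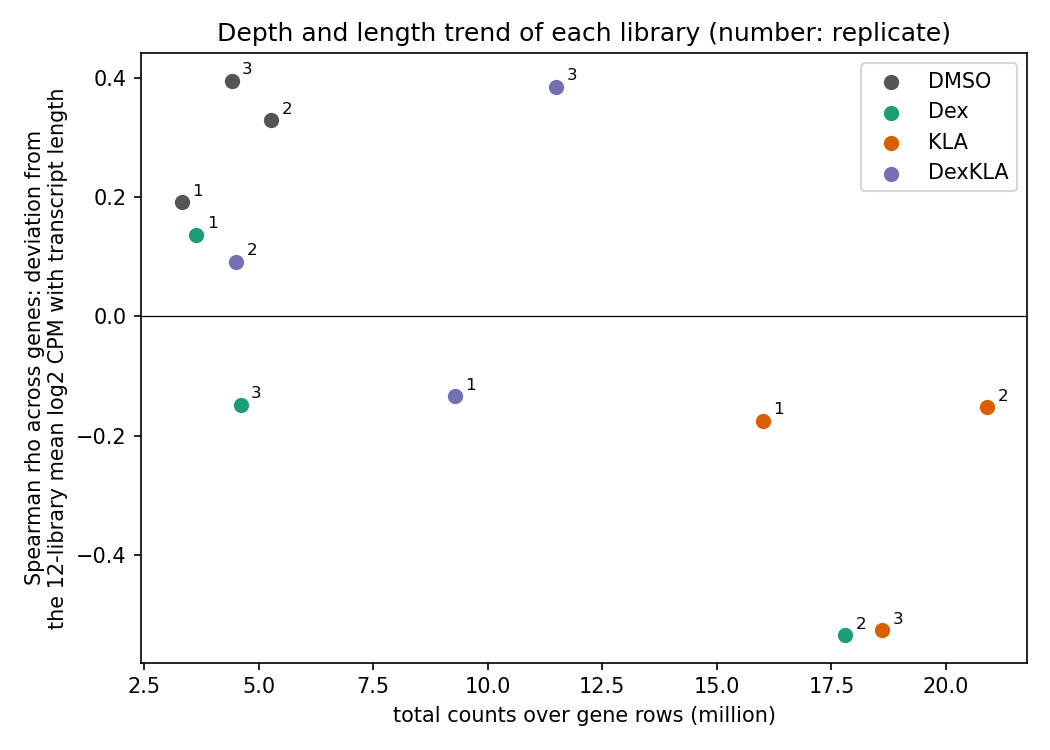
Total gene counts per library, in units of 1e+06, against Spearman's rho, across genes, of the library's deviation from the mean of all 12 with transcript length, with points coloured by group and numbered by replicate. DMSO libraries had the fewest counts (3.32 to 5.28, with Dex replicates 1 and 3 and DexKLA replicate 2 beside them) and positive rho (0.192 to 0.395), and KLA libraries had 16 to 20.9, with Dex replicate 2 at 17.8, and negative rho.

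HepG2 cells expressed NR3C1, the glucocorticoid receptor (chromosome 5, 143277934 to 143403686, minus strand), at 32.8 ± 3.8 CPM with DMSO, 28 ± 6.44 with Dex, 26.4 ± 5.24 with KLA and 29.8 ± 2.44 with DexKLA. It was not called in any comparison. FKBP5, a chaperone partner of the receptor and a well-known target of glucocorticoids (chromosome 6, 35573585 to 35728583, minus strand), stood at 25.7 ± 3.38, 37.6 ± 1.94, 19.3 ± 4.68 and 39.3 ± 8.23 CPM in the same order. Its rise with Dex alone was not called (log2 0.55 ± 0.17, adjusted p = 0.0856, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and its rise with Dex in the presence of KLA was (1.04 ± 0.16, adjusted p = 0.000867). The difference between both rises was not past the threshold (0.49, adjusted p = 0.223). TSC22D3, another common glucocorticoid target, had 3 to 22 counts per library and was not tested. TLR4 had 0 to 9 counts per library, at or under 0.907 CPM, and was not tested. Its 0 counts in Dex replicates 1 and 3 allow up to 0.824 and 0.65 CPM. LY96, the partner of TLR4, was near the floor (1.36 ± 0.21 CPM with DMSO and 2.38 ± 0.661 with KLA, adjusted p = 0.191). CD14, a co-receptor for lipopolysaccharide, was lower with KLA (6.41 ± 3.73 to 2.81 ± 0.923 CPM, log2 −1.10 ± 0.33, adjusted p = 0.0332) and with DexKLA (1.82 ± 0.797 CPM, −1.72 ± 0.39, adjusted p = 0.0203). DMSO replicate 1 held 11.5 CPM of CD14 against 4.17 and 4.76 in the other DMSO libraries. CD14 was no longer called in KLA versus DMSO without DMSO replicate 1 or KLA replicate 3, nor in DexKLA versus DMSO without DMSO replicate 1 or DexKLA replicate 2.

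Dex alone raised HIF3A, an alpha subunit of the hypoxia-inducible factors, from 0.226 ± 0.0516 to 7.9 ± 0.133 CPM (chromosome 19, 46303619 to 46343433, plus strand). It also raised HOMER2, a scaffold protein of the Homer family (6.96 ± 0.76 to 26.9 ± 1.67 CPM, chromosome 15, 82848984 to 82952720, minus strand), DKK4, a secreted Wnt antagonist (8.85 ± 1.9 to 27.9 ± 3.71), and SLC26A3, a chloride and bicarbonate exchanger (10.3 ± 2.39 to 30.8 ± 1.95). CYP24A1, which inactivates vitamin D, fell from 39.5 ± 18.4 to 11 ± 0.236 CPM (chromosome 20, 54153446 to 54173986, minus strand), and SLC51B, a subunit of the bile acid exporter of the basolateral membrane, fell from 20.9 ± 6.72 to 7.05 ± 0.964. AFP, the alpha-fetoprotein made by fetal liver and by hepatomas, rose from 15300 ± 1380 to 33500 ± 1750 CPM (chromosome 4, 73436221 to 73456174, plus strand).

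In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes with Dex were 5.10 ± 0.42 for HIF3A (adjusted p = 3.01e-07), 1.93 ± 0.17 for HOMER2 (3.9e-07), 1.63 ± 0.25 for DKK4 (0.000828), 1.56 ± 0.20 for SLC26A3 (0.000112), 1.13 ± 0.15 for AFP (0.000189), −1.80 ± 0.27 for CYP24A1 (0.000726) and −1.48 ± 0.23 for SLC51B (0.000985). HIF3A had 1 count in each DMSO library, under the floor of 3 counts, so its fitted change is uncertain. Its ratio of pooled counts was 34, with a 95% counting interval of 11.5 to 166. The enzyme gene GNMT, which lies within the readthrough gene CNPY3-GNMT and opposite PEX6, rose from 4.88 ± 2.27 to 13.4 ± 1.8 CPM (adjusted p = 0.00159). In all, 270 of 13166 genes were called in Dex versus DMSO, 160 higher and 110 lower, with a median absolute log2 change of 0.63. Of these, 35 changed over 2-fold, 26 higher and 9 lower. Genes called higher had a median transcript length of 1548 bases and those called lower 4878, against 3130 for all tested genes. The count was 66, 124 and 97 without DMSO replicates 1, 2 and 3, 56 and 72 without Dex replicates 2 and 3, 915 without KLA replicate 3 and 728 without DexKLA replicate 3. Called in each of the 12 fits that leave out 1 library were 39 genes, 29 higher and 10 lower, among them the genes of this paragraph. With library size alone as the scaling, the median of all genes was −0.11 in place of −0.011 and 26.3% of the called genes were higher in place of 59.3%.

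Among glucocorticoid receptor targets with Dex alone, CEBPD, a transcription factor of the acute-phase response, rose (log2 0.76 ± 0.16), while SGK1, a kinase that regulates ion transport, and PIK3R1 fell (SGK1 −0.79 ± 0.14, 42.7 ± 2.01 to 24.7 ± 1.09 CPM, adjusted p = 0.00358, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over the list of 26 tested targets, 1 was called higher, 2 lower and 23 not, with 5 higher and 2 lower when adjusted over the list alone, a median of 0.20 and a camera adjusted p = 0.642 (adjusted p = 0.89 with an estimated correlation). Acute-phase genes moved down on balance. FGA and FGB, chains of fibrinogen, fell (FGA from 1890 ± 317 to 948 ± 15.1 CPM, log2 −0.99 ± 0.12, adjusted p = 5.67e-05), while MT2A, a metal-binding protein that glucocorticoids induce, rose from 113 ± 18.2 to 194 ± 19.1 CPM (0.79 ± 0.13, adjusted p = 0.00303). Of 23 acute-phase genes 2 were called higher, 3 lower and 18 not (3 and 9 adjusted over the list alone, camera adjusted p = 0.00104 downward, adjusted p = 0.313 with an estimated correlation). Of 41 coagulation and complement genes, 1 was called higher and 4 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.00202 downward, adjusted p = 0.286 with an estimated correlation). They included MBL2, the lectin that starts a complement pathway, which fell by 1.02 on the log2 scale. The calls of SGK1, FGA and MT2A held without each library, and those of CEBPD, PIK3R1, FGB and MBL2 did not.

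Genes of fatty acid and triglyceride synthesis were lower with Dex alone than with DMSO. ACSL3, which activates fatty acids, fell by 0.64 on the log2 scale. ACACA (with 2 annotated loci) and FASN, the enzymes that build fatty acids, and SREBF1, their transcription factor, which lies opposite RAI1, fell by 0.75, 0.61 and 0.64. The list had 24 tested members, 5 lower and none higher (14 lower adjusted over the list alone, median −0.29, camera adjusted p = 4.26e-09, adjusted p = 0.286 with an estimated correlation). In DexKLA versus KLA, which uses no DMSO library, the list did not fall. None of its members was called there (1 lower adjusted over the list alone, median 0.10, camera adjusted p = 0.721). Apolipoproteins and hepatocyte secretory proteins moved up against DMSO, with 6 of 31 called higher and 1 lower (9 and 3 adjusted over the list alone, median 0.23 and 0.13 with library size alone, camera adjusted p = 7.43e-05, adjusted p = 0.538 with an estimated correlation). In DexKLA versus KLA this list had a median of 0, with 2 called higher and 1 lower (camera adjusted p = 0.785). It was called higher there only with the trends on length and GC content removed (camera adjusted p = 0.0205). With Dex alone, IGFBP2, which binds insulin-like growth factors, rose from 19.8 ± 1.47 to 44.7 ± 3.69 CPM (log2 1.19 ± 0.14, adjusted p = 6.44e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and APOC1 and APOC2, which sit on lipoproteins, rose by 0.70 and 0.66. APOC2 lies within the readthrough gene APOC4-APOC2. CEBPA, a main transcription factor of hepatocytes (chromosome 19, 33299934 to 33302564, minus strand), fell from 337 ± 40.9 to 187 ± 12.9 CPM (−0.85 ± 0.12, adjusted p = 0.00047). DUSP6, a phosphatase that switches off the kinase ERK, rose from 121 ± 15.9 to 257 ± 16.6 CPM (1.07 ± 0.12, adjusted p = 3.73e-05). CYP3A5, a drug-metabolising enzyme gene of the class that glucocorticoids induce, which lies opposite ZSCAN25, rose by 1.15 ± 0.20 (adjusted p = 0.00324), a call that ended without Dex replicate 2. The ribosomal protein genes, kept as a check of RNA quality, moved up too (4 of 26 called higher and 13 adjusted over the list alone, median 0.27 and 0.17 with library size alone, camera adjusted p = 8.35e-11, adjusted p = 0.538 with an estimated correlation), and the nuclear-retained and long noncoding RNAs had a median of 0.27 (camera adjusted p = 0.0637). Of the synthesis genes, only ACSL3 was called without each library in turn, and IGFBP2, APOC1, APOC2, CEBPA and DUSP6 were too.

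**Figure D2:**
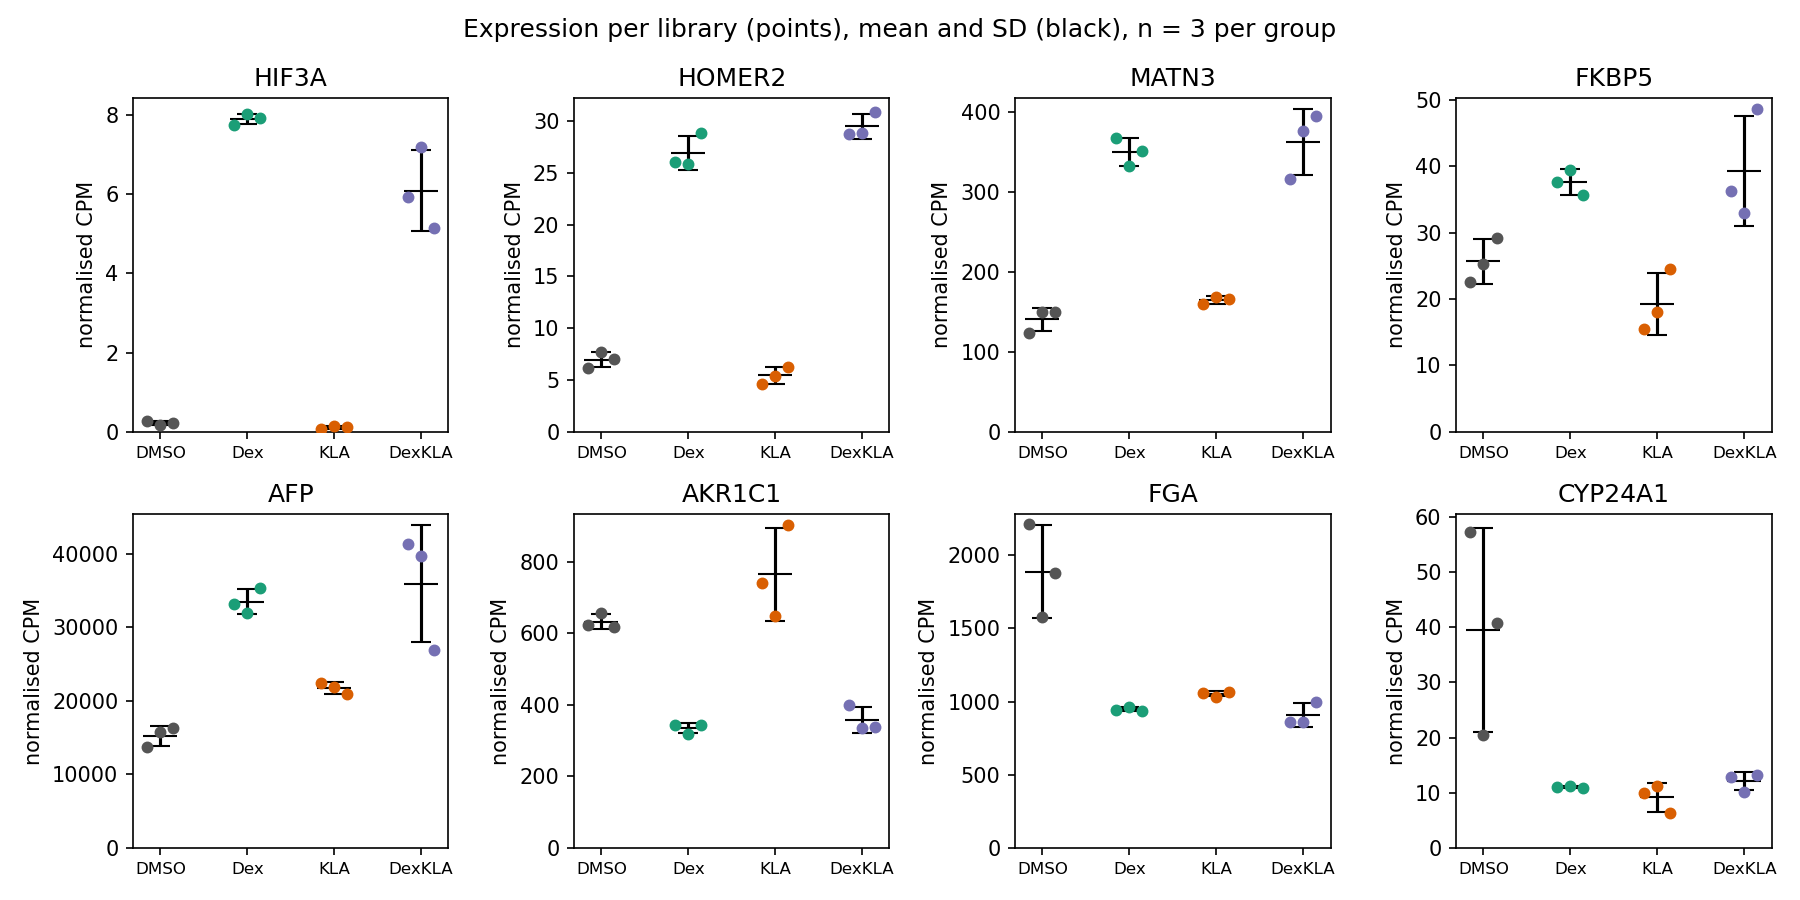
Normalised CPM of 8 genes in each library (points) with mean ± SD of 3 libraries per group, for DMSO, Dex, KLA and DexKLA. HIF3A stood at 0.226 and 0.107 CPM without Dex, at 1 to 3 counts per library, and at 7.9 and 6.1 with it, and CYP24A1 stood at 39.5 CPM with DMSO and at 9.15 to 12.1 in the 3 treated groups.

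Dex in the presence of KLA again raised HIF3A (0.107 ± 0.0406 to 6.1 ± 1.03 CPM) and HOMER2 (5.43 ± 0.819 to 29.5 ± 1.22). It raised MATN3, a matrix protein of cartilage (165 ± 4.76 to 363 ± 41.3 CPM, chromosome 2, 19992052 to 20012668, minus strand), CAVIN2, a coat protein of caveolae (33.8 ± 1.63 to 75.3 ± 10.7), and PGC, a pepsinogen (48 ± 11.1 to 121 ± 16.6). AKR1C1, which inactivates progesterone, fell from 765 ± 129 to 358 ± 35.7 CPM (chromosome 10, 4963415 to 4983282, plus strand), and SLC6A14, an amino acid transporter, fell from 3.56 ± 0.527 to 0.605 ± 0.122. These 7 genes stayed called without each library in turn. AKR1B10 and ALDH1A1, enzymes that oxidise or reduce aldehydes, were lower as well.

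The log2 changes of DexKLA versus KLA were 5.59 ± 0.33 for HIF3A (adjusted p = 3.47e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 2.44 ± 0.14 for HOMER2 (3.47e-10), 1.14 ± 0.11 for MATN3 (1.62e-06), 1.16 ± 0.12 for CAVIN2 (4.58e-06), 1.33 ± 0.15 for PGC (3.21e-05), −1.09 ± 0.12 for AKR1C1 (1.04e-05) and −2.46 ± 0.35 for SLC6A14 (0.000353). HIF3A had 1 to 3 counts in each KLA library, and its ratio of pooled counts was 53.1, with a 95% counting interval of 23.8 to 147. In all 86 genes were called in DexKLA versus KLA, 58 higher and 28 lower, with a median absolute change of 0.79. Without DexKLA replicates 2 and 3 the count was 52 and 55. Of these genes, 35 were called in each of the 12 fits that leave out 1 library. Of the glucocorticoid receptor targets, 3 of 26 were called higher and none lower (4 higher adjusted over the list alone, median 0.16, camera adjusted p = 2.89e-05, adjusted p = 0.532 with an estimated correlation). They were FKBP5, the transcription factor KLF9 (0.94) and the EGF receptor inhibitor ERRFI1 (0.79), the last pair chosen after their values were seen. Acute-phase genes were lower (2 of 23 called lower and none higher, 2 higher and 9 lower adjusted over the list alone, median −0.22, camera adjusted p = 2.89e-05, adjusted p = 0.251 with an estimated correlation). So were coagulation and complement genes (2 of 41 called lower, 3 adjusted over the list alone, median −0.13, camera adjusted p = 0.000129, adjusted p = 0.189 with an estimated correlation). Ribosomal protein genes were lower here with none called (median −0.18, camera adjusted p = 3.1e-06, adjusted p = 0.745 with an estimated correlation), opposite to Dex alone.

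Averaged over cells without and with KLA, Dex changed other single genes besides HIF3A and HOMER2. PTGDR2, a receptor for prostaglandin D2 that lies opposite CCDC86, rose by 1.31 ± 0.12 on the log2 scale, MATN3 by 1.22 ± 0.08 and PGC by 1.29 ± 0.11. FURIN, a protease that matures secreted proteins, fell by 0.73 ± 0.10, FST, which binds activin, fell by 0.64 ± 0.09, CEBPA fell by 0.66 ± 0.09 and AKR1C1 fell by 1.01 ± 0.08. The fibrinogen chains FGA (−0.60) and FGB (−0.54) were lower, and so were HAMP, the iron hormone hepcidin (−1.09), and SERPINA3 (−0.45), while MT2A was higher (0.63). Against DMSO, FGA changed by −0.99 with Dex, −0.84 with KLA and −1.06 with DexKLA. Most of its mean fall thus came from Dex versus DMSO. The members of lists in this paragraph were chosen after their values were seen.

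Of the 13166 genes, 199 were called for Dex averaged over KLA (115 higher, 84 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 8e-12 for HIF3A (5.34 ± 0.26) and for HOMER2 (2.18 ± 0.11), 5.97e-10 for MATN3, 1.05e-07 for AKR1C1 and 6.13e-05 for CEBPA. Without KLA replicate 3 the count was 317, and 107 genes were called without each library in turn. With library size alone, 45.7% of the called genes were higher in place of 57.8%. Of 41 coagulation and complement genes 7 were called lower and none higher (1 higher and 9 lower adjusted over the list alone, median −0.14), with a camera adjusted p = 5.44e-08 (adjusted p = 0.0291 with an estimated correlation). This was the only call of a list, out of 48, that held with the estimated correlation. Acute-phase genes were 2 higher and 5 lower of 23 (3 and 13 adjusted over the list alone, median −0.26, camera adjusted p = 5.2e-09, adjusted p = 0.0517 with an estimated correlation). Glucocorticoid receptor targets were 5 higher and 1 lower of 26 (7 and 2 adjusted over the list alone, median 0.08, camera adjusted p = 0.000793, adjusted p = 0.488 with an estimated correlation).

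The response to Dex without and with KLA was compared between libraries that shared no control. Of the genes called in Dex versus DMSO, 30 were called higher in both (0.705 expected by chance, one-sided Fisher p = 4.36e-43 across genes) and 7 lower in both (0.234 expected, p = 2.4e-09). Of the 86 genes called in DexKLA versus KLA, 78 (90.7%, 95% interval 82.5% to 95.9%) had the same sign in Dex versus DMSO. In the other direction only 141 of 270 (52.2%, 46.1% to 58.3%) had the same sign. Over the genes then called, this share was 84.8% without DMSO replicate 1, 83.9% without Dex replicate 2 and 80.6% without Dex replicate 3. This concordance of the Dex effect without and with KLA was lowest, at 39.7%, without Dex replicate 1. Across all genes, the log2 changes did not rise together (r = −0.0757, Spearman's rho −0.284). These changes had opposite trends with transcript length. Spearman's rho between change and length was −0.448 in Dex versus DMSO and 0.494 in DexKLA versus KLA. Over the genes called in Dex versus DMSO, which were chosen by that change, r was 0.634. Their median signed change was 0.63 without KLA and 0.03 with it, so the typical gene among them did not move along.

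**Figure D3:**
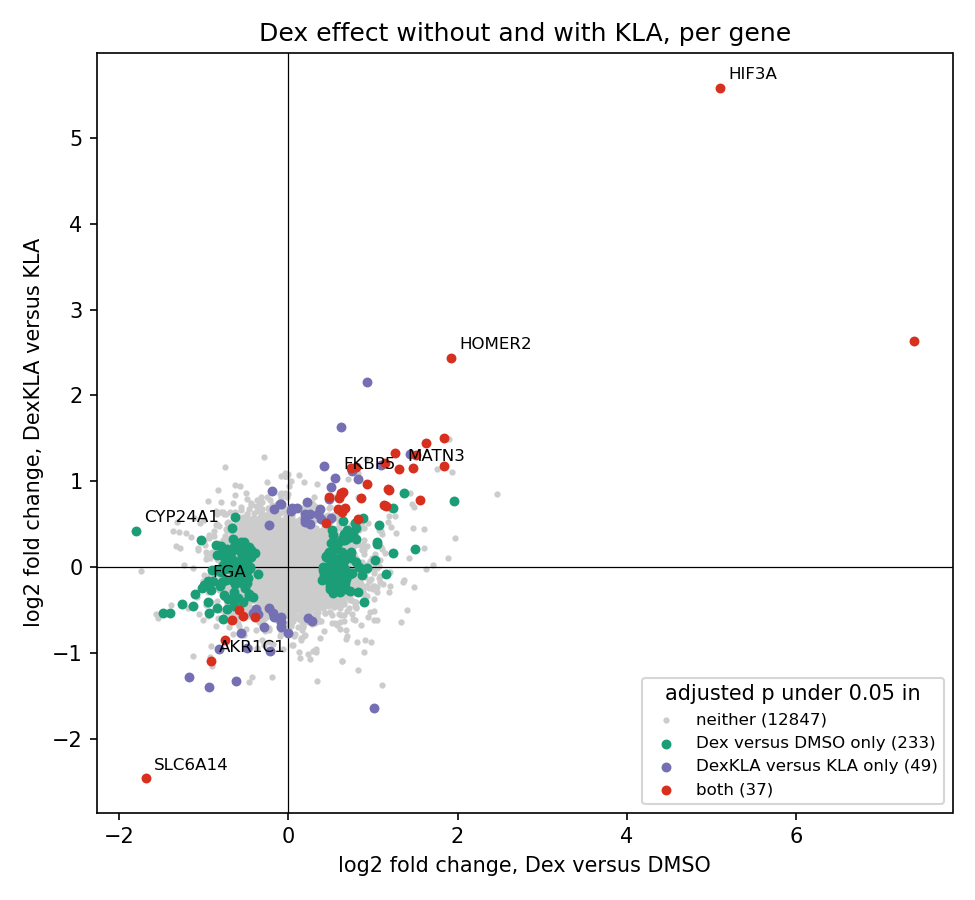
Log2 fold change of Dex versus DMSO (horizontal) against DexKLA versus KLA (vertical) for each tested gene, with genes called in both marked. Genes called in both numbered 30 higher and 7 lower, while r over all genes was −0.0757.

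KLA alone lowered CYP24A1 (39.5 ± 18.4 to 9.15 ± 2.55 CPM) and FGA (1890 ± 317 to 1050 ± 16.7) and raised IER3, an immediate early gene of stress and NF-kB signalling (81.2 ± 4.81 to 156 ± 27.7 CPM, chromosome 6, 30743199 to 30744547, minus strand, with 6 annotated loci and opposite IER3-AS1). CCL20, a chemokine that NF-kB induces, rose from 253 ± 46.8 to 528 ± 175 CPM (chromosome 2, 227813842 to 227817556, plus strand). G6PC and PCK1, enzymes of glucose output, fell, and so did FASN, ACACA and the fatty acid oxidation enzyme CPT1A. ANKRD37, a target of hypoxia-inducible factors that lies opposite UFSP2, rose from 7.97 ± 2.53 to 22.3 ± 8.95 CPM. Of these genes, only CYP24A1, FGA and IER3 stayed called without DMSO replicate 1.

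The log2 changes with KLA were −2.08 ± 0.25 for CYP24A1 (adjusted p = 0.000357, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), −0.84 ± 0.12 for FGA (0.0011), 0.94 ± 0.13 for IER3 (0.0011), 1.06 ± 0.23 for CCL20 (0.0107), −1.10 ± 0.18 for G6PC (0.00671), −0.80 ± 0.16 for FASN (0.00914), −0.98 ± 0.15 for CPT1A (0.00453) and 1.43 ± 0.30 for ANKRD37 (0.0105). In all 1807 genes were called in KLA versus DMSO, 1024 higher and 783 lower, with a median absolute change of 0.50, and 27 of them changed over 2-fold. Without DMSO replicate 1 the count was 5, without DMSO replicates 2 and 3 it was 897 and 895, and without KLA replicate 3 it was 591. With the depth class of the library as a covariate it was 4. The 5 genes called without DMSO replicate 1 were CYP24A1 (−1.72, adjusted p = 0.0138), FGA (−0.71) and IER3 (0.99), and PRKAR1A (−0.73) and RASSF7 (0.75, with 2 annotated loci), a pair chosen after its values were seen. Genes called higher had a median transcript length of 1622 bases and those called lower 5830. With library size alone, the median of all genes was −0.13 in place of −0.018 and 23.7% of the called genes were higher in place of 56.7%.

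The lists for inflammation moved little with KLA. NF-kB targets had 2 of 19 called higher and none lower (2 adjusted over the list alone), a median of −0.09 with a mean of 0.10, and a camera adjusted p = 0.588 (adjusted p = 0.792 with an estimated correlation). Of 31 interferon response genes, IFI6 was higher and MX2 lower, none when adjusted over the list alone, with a camera adjusted p = 0.995. Of 21 genes of TLR4 signalling, TBK1 was higher (0.50) and TAB2 (−0.46) and TRAF3 (−0.58) were among 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.535, adjusted p = 0.792 with an estimated correlation). Acute-phase genes were split, 3 higher and 3 lower of 23 (4 and 4 adjusted over the list alone, camera adjusted p = 0.553). Fatty acid and triglyceride synthesis was lower (9 of 24 called lower and none higher, 11 lower adjusted over the list alone, median −0.35, camera adjusted p = 1e-06, adjusted p = 0.714 with an estimated correlation). Insulin and IGF signalling genes were 1 higher and 6 lower of 28 (2 and 10 adjusted over the list alone, median −0.29, camera adjusted p = 0.0198), and liver transcription factors also 1 higher and 6 lower of 28 (2 and 9 adjusted over the list alone, median −0.26, camera adjusted p = 0.0198). With an estimated correlation, both had an adjusted p = 0.714. Glycolysis and hypoxia genes were higher (6 of 30 and none lower, 8 adjusted over the list alone, median 0.16 and 0.05 with library size alone, camera adjusted p = 0.0119, adjusted p = 0.714 with an estimated correlation). Against DMSO, this list was also called higher with Dex (camera adjusted p = 0.00505) and with DexKLA (0.0289). The liver transcription factors were also called lower with Dex (camera adjusted p = 0.0291) and with DexKLA (0.0201), so neither shift was particular to KLA. None of these calls held with an estimated correlation. Ribosomal protein genes were higher as well (10 of 26 and none lower, 13 adjusted over the list alone, median 0.29 and 0.18 with library size alone, camera adjusted p = 2.98e-07, adjusted p = 0.714 with an estimated correlation). The nuclear-retained and long noncoding RNAs, another check of RNA quality, were higher with none of 5 called (2 higher adjusted over the list alone, median 0.36, camera adjusted p = 0.0407, adjusted p = 0.714 with an estimated correlation). Without DMSO replicate 1 the calls of the liver transcription factor list (adjusted p = 0.0601) and of the noncoding RNA list (adjusted p = 0.199) ended, and that of the insulin and IGF list ended with the trends on length and GC content removed (adjusted p = 0.167). The called members of the lists in this paragraph lost their calls without DMSO replicate 1, except FGA and IER3.

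DexKLA against DMSO raised HIF3A, HOMER2, DKK4 and SLC26A3 and lowered CYP24A1 and FGA. HAMP fell from 9.11 ± 1.44 to 3.43 ± 1.58 CPM, a call lost without DMSO replicate 1. SLC6A14 was lower too, a call lost without DMSO replicate 2. AFP rose to 36000 ± 7920 CPM, and IGFBP2 and DUSP6 rose while CEBPA fell.

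The log2 changes were 4.68 ± 0.44 for HIF3A (adjusted p = 1.58e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 2.07 ± 0.16 for HOMER2 (1.41e-07), 1.87 ± 0.24 for DKK4 (0.000118), −1.65 ± 0.26 for CYP24A1 (0.00122), −1.06 ± 0.12 for FGA (1.58e-05), −1.48 ± 0.31 for HAMP (0.0133), −2.08 ± 0.43 for SLC6A14 (0.0109), 1.24 ± 0.15 for AFP (7.46e-05), 1.33 ± 0.14 for IGFBP2 (1.01e-05), 1.20 ± 0.12 for DUSP6 (4.77e-06) and −0.92 ± 0.12 for CEBPA (0.00015). The ratio of pooled counts of HIF3A was 24.9, with a 95% counting interval of 8.34 to 122. In all 557 genes were called in DexKLA versus DMSO, 375 higher and 182 lower, and 37 of them, 25 higher and 12 lower, without each library in turn. The count was 48, 202 and 247 without DMSO replicates 1, 2 and 3, 95, 88 and 1461 without DexKLA replicates 1, 2 and 3, 273 without Dex replicate 3 and 1079 without KLA replicate 3. With library size alone, the median of all genes was −0.115 in place of −0.017 and 27.7% of the called genes were higher in place of 67.3%, and 47.3% were with the trends on length and GC content removed. Acute-phase genes were 2 higher and 7 lower of 23 (2 and 12 adjusted over the list alone, median −0.32, camera adjusted p = 3.75e-05, adjusted p = 0.258 with an estimated correlation). Coagulation and complement genes were 1 higher and 7 lower of 41 (2 and 14 adjusted over the list alone, median −0.26, camera adjusted p = 3.75e-05, adjusted p = 0.139 with an estimated correlation). Glucocorticoid receptor targets were 4 higher and 1 lower of 26 (4 and 4 adjusted over the list alone, median 0.15, camera adjusted p = 0.397, adjusted p = 0.765 with an estimated correlation). Of the checks of RNA quality, ribosomal protein genes had a median of 0.12 (0 with library size alone, camera adjusted p = 0.0519), and the nuclear-retained and long noncoding RNAs were higher (median 0.39, camera adjusted p = 0.0278, adjusted p = 0.386 with an estimated correlation), a call that ended without DMSO replicate 1 (adjusted p = 0.156).

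**Figure D4:**
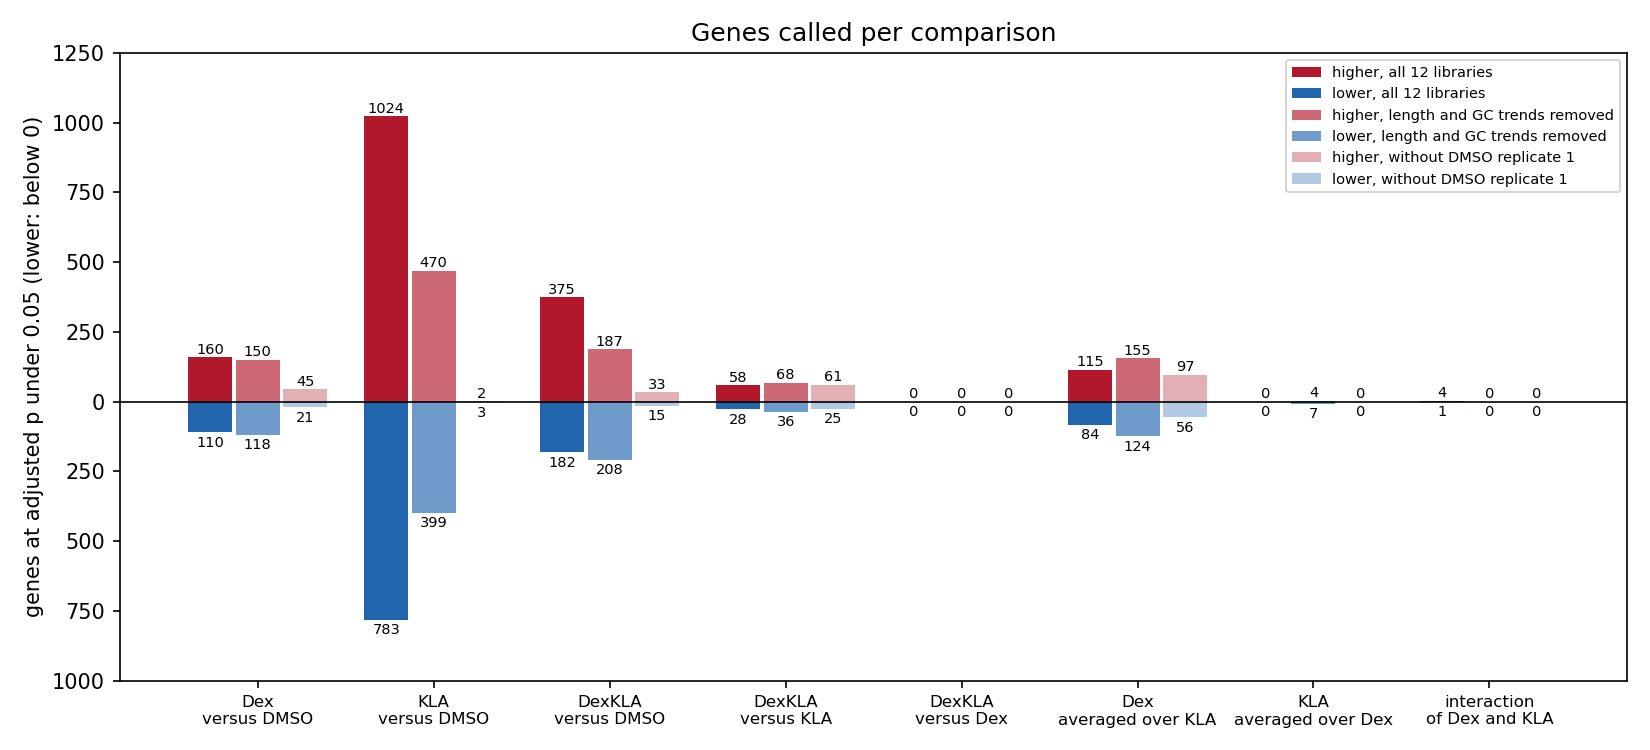
Genes called higher (above 0) and lower (below 0) in each of the 8 comparisons, with all 12 libraries, with the trends on transcript length and GC content removed, and without DMSO replicate 1. KLA versus DMSO had 1807 calls with all libraries, 869 with the trends removed and 5 without DMSO replicate 1.

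With Dex present, KLA changed no gene past the threshold. CCL20, IER3, FGA and CYP24A1, which differed between KLA and DMSO, were not called in DexKLA versus Dex. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in DexKLA versus Dex, with 934 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each. Without the filter on low counts edgeR called 12. In the same test, a planted 2-fold change was called for 89.6% of simulated genes and a 1.5-fold change for 43.3%. Lists moved by small amounts with none of their members called. Ribosomal protein genes were lower (median −0.17, camera adjusted p = 1.55e-09), and so were apolipoproteins and secretory proteins (−0.12, camera adjusted p = 0.00225) and genes of the unfolded protein response (−0.13, camera adjusted p = 0.003). With an estimated correlation each of these had an adjusted p = 0.643. With the trends on length and GC content removed, the call of the apolipoproteins ended (adjusted p = 0.0897). NF-kB targets had a median of 0.13 and a camera adjusted p = 0.153 (adjusted p = 0.643 with an estimated correlation), and were called higher at the preset correlation with the trends removed (adjusted p = 0.00386).

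Averaged over cells without and with Dex, KLA likewise changed no gene past the threshold. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes for KLA averaged over Dex, with 2533 at an unadjusted p under 0.05, while DESeq2 called 613 and limma voom 0. Without DexKLA replicate 3 edgeR called 986, without DMSO replicate 2 and without KLA replicate 2 it called 4 each, and without KLA replicate 3 it called 1. Fatty acid and triglyceride synthesis was lower (median −0.14, camera adjusted p = 0.000229, adjusted p = 0.587 with an estimated correlation), and so was the unfolded protein response (−0.12, camera adjusted p = 0.000229, adjusted p = 0.587 with an estimated correlation), with no member of either called. The nuclear-retained and long noncoding RNAs were higher (median 0.20, camera adjusted p = 0.0455, adjusted p = 0.587 with an estimated correlation), a call that ended without DMSO replicate 1 (adjusted p = 0.107). NF-kB targets were called higher with the trends on length and GC content removed at the preset correlation (adjusted p = 0.0495, against 0.165 before and 0.601 with an estimated correlation before). Of the genes called in KLA versus DMSO, 778 of 1807 (43.1%, 95% interval 40.8% to 45.4%) had the same sign in DexKLA versus Dex, which shares no library with it. Across all genes r was −0.0994. Here too the trends with transcript length were opposite, with Spearman's rho −0.467 in KLA versus DMSO and 0.389 in DexKLA versus Dex. Over the genes then called, the share was 29.1% without DexKLA replicate 1 and 67.1% without DexKLA replicate 3.

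The test of whether the effect of Dex differed with KLA called 5 genes, which include CYP24A1, HIPK1, a nuclear kinase, and PRKAR1A, a regulatory subunit of protein kinase A. Of these, 0 stayed called without each library in turn. The DMSO libraries enter this test, so a difference between them and all treated groups would also give such a term. CYP24A1 fell with each treatment and fell no further with both, so its interaction was positive. MYCBP2, a ubiquitin ligase, HIPK1 and PRKAR1A also had lower mean CPM with Dex and with KLA than with DMSO. RPPH1, the RNA of ribonuclease P, had the opposite form, with 2.48 CPM with DMSO, 5.52 with Dex, 6.22 with KLA and 2.09 with DexKLA.

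The terms for the interaction of Dex and KLA were 2.23 ± 0.37 for CYP24A1, 1.21 ± 0.22 for MYCBP2, 1.11 ± 0.19 for HIPK1, 0.82 ± 0.15 for PRKAR1A and −2.66 ± 0.48 for RPPH1, each with an adjusted p = 0.045 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2926 genes, DESeq2 called 672 and limma voom 0. The count was 0 without DMSO replicate 1, Dex replicate 2, Dex replicate 3, DexKLA replicate 2 or DexKLA replicate 3. It was 1 without DMSO replicate 3, 2 without KLA replicate 1, 8 without KLA replicate 3, 430 without Dex replicate 1, 418 without KLA replicate 2 and 681 without DexKLA replicate 1. With library size alone, the median of all genes was 0.129 in place of 0.016.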

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

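The tests of depth and of trends with transcript length and GC content, and the tests on the interaction and on the pair of Dex responses were chosen after the results were seen. The tests of 1 DMSO library, of a KLA response that Dex removes and of other splits were not.

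Genes called in the interaction test were CYP24A1 (log2 2.23), MYCBP2 (1.21), PRKAR1A (0.82), HIPK1 (1.11) and RPPH1 (−2.66). Among the lists, camera called the interaction of fatty acid and triglyceride synthesis (median 0.41), apolipoproteins and hepatocyte secretory proteins (−0.26), glycolysis and hypoxia (−0.22) and ribosomal proteins (−0.48). No member of these lists was called, and none of the 4 lists passed with an estimated correlation (adjusted p = 0.888 each). The call of the apolipoproteins ended with the trends on length and GC content removed (adjusted p = 0.857), and that of glycolysis and hypoxia ended without DMSO replicate 1 (adjusted p = 0.0629). A further flagged difference lay in transcripts without a gene symbol that the gene tests did not use, the ribosomal RNAs of the mitochondrion, at positions 648 to 1601 and 1671 to 3229 of its genome. As a share of the gene counts plus their own, a smaller total than that of all transcripts, they held 4.52% with Dex (SD 0.285), 4.71% with KLA (0.286) and 4.89% with DexKLA (0.528), against 3.96% with DMSO (0.402). The differences of 0.562, 0.748 and 0.923 points each had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give, and no explanation of them was tested. A group was flagged only if each of its libraries lay above all DMSO libraries. That rule fixes this p-value in advance, so the test adds nothing to it. The differences also share the same DMSO libraries.

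The first pattern was the 1807 genes called in KLA versus DMSO. Of these, 1249 were called in the same direction after every library was thinned to the shallowest total. This argued against the number of reads as the whole cause. Thinning leaves in place any other difference between libraries that goes with depth. With the depth class as a covariate 4 genes were called, while the median signed change of the 1807 was 0.47 (SD 0.21) and their median standard error 0.19 in place of 0.13, so the calls ended with the wider error. All DMSO libraries were in the shallower class and all KLA libraries in the deeper. The covariate thus rested on the Dex and DexKLA libraries and cannot separate KLA from what goes with depth. To weigh a single aberrant DMSO library as the source, DMSO replicate 1 was left out. The median signed change of the 1807 genes was then 0.45, against 0.50 with all libraries and 0.52 without each of the other DMSO libraries. These genes had been picked with the same KLA libraries and the other DMSO libraries, so part of that size follows from the choice. Only 5 genes were called without DMSO replicate 1, and its share in the changes stays open. The trend with transcript length and GC content was argued against for the 609 genes still called once it was removed, while for 1184 genes that lost their call the median went from 0.48 to 0.24 (SD 0.14) and cause and trend cannot be told apart. A KLA response that Dex removes was argued against for these genes as a set, not for each gene. The distance of KLA from the groups with Dex was a median of 0.284 of its distance from DMSO (quartiles 0.171 and 0.404). The genes were chosen for that distance from DMSO, which lowers the ratio. The DMSO libraries may be the ones that stand apart, whether from a technical difference or from a response shared by all treatments, and the design leaves both open. Since the labels do not say whether treated cells received DMSO, an effect of the vehicle itself cannot be told apart from these either.

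The second pattern was the 5 interaction genes. The number of reads as the cause was argued against, since all 5 were called in the same direction after thinning. With the depth class as a covariate, where 0 were called, their median was 1.12 with a median standard error of 0.25 in place of 0.22. With the trends on length and GC content removed the median fell from 1.21 to 0.79 and 0 of the 5 were called. CYP24A1 kept its size (2.23 ± 0.37 before, 2.16 ± 0.39 after) and missed the threshold with an adjusted p = 0.0679 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PRKAR1A (0.82 ± 0.15 to 0.74 ± 0.14) and RPPH1 (−2.66 ± 0.48 to −2.21 ± 0.52) kept most of theirs. HIPK1 shrank from 1.11 ± 0.19 to 0.76 ± 0.15 and MYCBP2 from 1.21 ± 0.22 to 0.79 ± 0.19. The trend and an interaction thus cannot be told apart at 3 libraries per group. Fits of 100 random splits gave 5, the real one included, with as many genes, and up to 978 genes, so chance could not be excluded. The splits with 764, 803 and 978 genes kept all KLA libraries against all DMSO libraries, so they hold the difference of KLA versus DMSO.

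The third pattern was the weak match of the Dex response without and with KLA, with 52.2% of Dex versus DMSO genes keeping their sign. With the trends on length and GC content removed the share was 70.9%, over the genes called in that fit. This lay outside the 95% interval of 46.1% to 58.3%, which treats genes as independent and leaves out the spread between libraries. Leaving out 1 library moved the share from 39.7% to 84.8%. The trend is thus a candidate explanation for part of the mismatch that these shares cannot settle. A response to Dex that KLA changes stays open, since 4 of the 270 genes passed the interaction test. Of the genes called in Dex versus DMSO with the trends removed, which are another set, 0 passed. Over that set, with the trends removed, the effect with KLA was a median of 0.303 of that without. Before the removal, the median signed changes of the 270 genes were 0.63 without KLA and 0.03 with it.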

How the results depend on the processing

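The tests after thinning, with the trends removed, with the depth class, in 1 depth class and without the pair of libraries farthest apart were chosen after the results were seen. The cause of the changes below was not tested, except that settings with fewer libraries have fewer degrees of freedom.

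Under the other settings, Dex versus DMSO (270 genes) called 680 with DESeq2, 907 with no filter, 1348 in its 6 libraries alone, 129 with the depth class as a covariate, 492 in the shallower libraries and 134 with the replicate block. KLA versus DMSO (1807) called 869 with the length and GC trend removed, 4 with the depth class and 5 without the 2 libraries farthest apart. DexKLA versus DMSO (557) called 955 with DESeq2, 327 with limma voom, 987 with no filter, 326 with the replicate block, 173 with the depth class, 183 without the 2 farthest and 902 in the shallower libraries. DexKLA versus KLA (86) called 204 with no filter, 38 in its 6 libraries, 54 thinned and 16 in the deeper libraries. DexKLA versus Dex (0) called 12 with no filter. Dex averaged over KLA (199) called 312 with no filter. KLA averaged over Dex (0) called 2 with library size alone, 613 with DESeq2, 663 with no filter, 42 thinned and 11 with the trends removed. The interaction of Dex and KLA (5) called 0 with DESeq2's size factors, limma voom, the replicate block, the trends removed, the depth class or without the 2 farthest, and 230 with library size alone, 672 with DESeq2, 1041 with no filter and 39 thinned.

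Each share of concordance is over the genes called under its own setting. For the concordance of the Dex effect without and with KLA (52.2%), library size alone gave 45.6%, the replicate block 66.4%, thinning 42.9%, the trends removed 70.9% and the depth class 70.5%. For the concordance of the KLA effect without and with Dex (43.1%), thinning gave 46.5%, the trends removed 50.9%, the depth class 75% and leaving out the 2 farthest 60%. The filter of 50 reads in 3 libraries and the longest transcript per gene left the count of each of the 8 comparisons within 1.5 times of that given. Of the calls of gene lists (48), 1 was made with the estimated correlation and 48 with the replicate block.

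Leaving out 1 library at a time, Dex versus DMSO ran from 56 (Dex replicate 2) to 915 (KLA replicate 3), KLA versus DMSO from 5 (DMSO replicate 1) to 2368 (DexKLA replicate 3), DexKLA versus DMSO from 48 (DMSO replicate 1) to 1461 (DexKLA replicate 3), DexKLA versus KLA from 52 (DexKLA replicate 2) to 94 (KLA replicate 3), DexKLA versus Dex from 0 to 0, Dex averaged over KLA from 139 (DexKLA replicate 1) to 317 (KLA replicate 3), KLA averaged over Dex from 0 to 986 (DexKLA replicate 3) and the interaction of Dex and KLA from 0 to 681 (DexKLA replicate 1). The concordance of the Dex effect without and with KLA ran from 39.7% to 84.8%, that of the KLA effect without and with Dex from 29.1% to 67.1%, and the gene lists from 38 (DMSO replicate 1) to 59 (KLA replicate 1).

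Of 237 calls of single named genes, not all of which had a value under each setting, none changed sign where there was one. Still called were 230 with DESeq2's size factors, 218 with library size alone, 215 with limma voom, 234 with no filter, 169 with the trends removed, 95 with the depth class, 113 without the 2 farthest, and 65, 168 and 149 without DMSO replicates 1, 2 and 3. The replicate block kept 197. Replicate numbers did not pair the libraries, since 0 of the 12 correlated best with a library of its own number once group means were removed. At the depth and spread of these libraries, which were not separated, a 1.5-fold change was called for 53.7% of simulated genes in Dex versus DMSO, 26.9% in the interaction and 86.6% in the mean effect of Dex.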

Other observations

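The splits of the libraries and the lists were chosen before the results were seen, and the comparison of each group with the other 3 after them.

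The DMSO libraries stood apart from all treated libraries more than any other group did. With 1 mean per group, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1723 genes between DMSO and the mean of the other groups (744 higher, 979 lower), against 81 for KLA, 27 for Dex and 32 for DexKLA. With the trends on transcript length and GC content removed, the counts were 1056, 109, 56 and 45. FGA, CYP24A1 and, in fatty acid synthesis, SREBF1 and ACACA were lower in both Dex and KLA than in the shared DMSO libraries, so that 1 set of controls carries each of these falls.

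Some responses usual for a glucocorticoid in liver cells were not called. Of genes of gluconeogenesis and amino acid catabolism, none of 23 was called higher with Dex and 2 were lower (3 lower adjusted over the list alone). Their median was 0.06 and their mean −0.05, with a camera adjusted p = 0.814. PCK1, the enzyme that commits carbon to glucose, fell (log2 −0.96 ± 0.20, adjusted p = 0.0133 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost without DMSO replicate 1 or Dex replicate 2. Genes of leukocytes, kept as a check for other cells, had 6 tested members with none called with Dex (camera adjusted p = 0.978). Extracellular matrix and TGF-beta genes had 4 of 29 lower with Dex than with DMSO and none higher (1 higher and 7 lower adjusted over the list alone, median −0.22, camera adjusted p = 0.000971, adjusted p = 0.286 with an estimated correlation). This list was also lower with KLA alone than with DMSO (1 higher and 5 lower, median −0.24, camera adjusted p = 0.0338, adjusted p = 0.714 with an estimated correlation). In DexKLA versus KLA, which uses no DMSO library, it was not called (median −0.11, camera adjusted p = 0.567).

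Other splits of the same libraries gave these counts. For Dex versus DMSO (270 genes, highest other split 0), KLA versus DMSO (1807, highest other 0), DexKLA versus DMSO (557, highest other 0) and DexKLA versus KLA (86, highest other 4), 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. For DexKLA versus Dex all 10 splits called 0, and for the mean effect of KLA all 100 splits reached the real count of 0 (highest 2026), which a count of 0 makes certain, so neither tally decides anything. For the mean effect of Dex, 3 of 100 splits called at least 199 genes, the highest other 821, a share under 0.05. Both other splits above the real count (821 and 500 genes) kept all Dex libraries against all DMSO libraries and regrouped only those with KLA, so they hold the difference of Dex versus DMSO, a structure of the samples. Other splits of this kind called 0 to 82 genes. The tally therefore does not settle whether the Dex label of the libraries with KLA adds to the count. For DMSO against the other 9 libraries in a fit of 2 groups, 1 of 100 splits called as many as 1512 genes, the highest other 375, a share under 0.05.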
